A study of Caenorhabditis elegans with 2 samples.

How the data were processed

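2 libraries of 1 seCLIP-seq experiment in C. elegans were compared, CAR-1(FL) and CAR-1(dSm), each taken from its sample title. The extraction protocol was not given in the sources used here, and no unbound or size-matched input library was used here, so a level of recovered RNA reflects both how much of an RNA was present and how much of it was pulled down. The submitters' processing notes name UMI-tools, cutadapt, STAR and SAMtools and the genome build ce10, without versions, roles or parameters. The peak caller, the gene annotation and the handling of reads that map to several places are not given in the sources used here.

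The authors deposited 2 peak lists, 1 per library. From its values, the first score of each peak is the authors' −log10 of a p-value, capped at 400, and the second is the authors' log2 fold of that library over the other; a −log10 p above 0 was found only where the log2 fold was positive. These values are the authors' own and were used to rank, count and describe peaks. The folds lie on a grid of ratios of whole numbers shifted by 0.44 in log2, which is a ratio of total reads of 1.36 between CAR-1(dSm) and CAR-1(FL). From a peak's fold and p the read numbers of both libraries were recovered by trying whole numbers under Fisher's exact test where a number was below 5 and a Yates-corrected chi-square otherwise. This worked for 94.4% and 100% of 1000 peaks drawn from each list, within a relative tolerance of 0.003 on −log10 p. No recovery was tried below a −log10 p of 0.1 or at the cap. A number of 1 in the other library can stand for 0.

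The authors also deposited an FPKM table per library, with a lower and an upper bound, in the column layout of Cufflinks per the file headers. FPKM scales fragments by transcript length and by the number of mapped fragments. The authors' bounds lie 2 standard errors from the value, so the implied number of fragments n follows from the upper bound divided by the FPKM, minus 1, being 2 over the square root of n; 60.9% and 59.5% of the genes came out within 0.05 of a whole number. The implied fragments summed to 233959 in CAR-1(FL) and 369072 in CAR-1(dSm). They and the bounds cover counting error and read assignment in 1 library, not the spread between cultures. An FPKM of 0 can be a failed estimate, so such a gene is described as listed at 0 and no fold is given. Rows of the 508 names with more than 1 row were summed, with their half-widths added in squares.

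A table of the authors' comparison was deposited in the column layout of Cuffdiff per the file headers, with FPKM values rescaled by the authors to about 5.13 and 5.25 times the per-library tables, a log2 fold, a test statistic used here for nothing (a score, per the file headers), a p-value and a q-value. Values quoted from it are the authors' and compare 2 libraries.

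What was computed here started from those files. Peaks past the thresholds had an authors' −log10 p of at least 3 and a log2 fold of at least 3. A peak was assigned to each gene locus of the expression tables it overlapped by 1 base, without regard to strand, because those tables give no strand; a named peak takes the shortest such locus. Exons, introns and UTRs are not described because the reference table at hand is of the assembly WBcel235, where 0.848% of 38808 shared names have the same start as in the files. That table was used only for gene types and synonyms, matching 41117 of 41560 names. Overlap between the lists required 1 base on the same strand.

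For FPKM, the difference was log2(FPKM + 1) in CAR-1(FL) minus that in CAR-1(dSm), over genes with an FPKM of at least 1 in either library. A gene was counted as higher at a difference of at least 1. With 1 library per group no p-value was computed. For each of 18 gene lists fixed before the data were examined, the median difference was placed among 10000 random lists of the same size matched on mean expression (each member replaced by one of its 50 nearest genes), as a description of these libraries; a list is said to lie outside the range where its median is outside their middle 95%. The lists were mitochondrial calcium handling, mitochondrial dynamics and transport, the nuclear respiratory chain, mitochondrial genome genes, mRNA decay and RNP granules, cytosolic ribosomal proteins, translation factors, axon regeneration regulators, synaptic and neuronal genes, calcium signalling, cytoskeleton, chaperones, muscle, germline and oocyte, sperm, intestine, epidermis and collagens, and histones. Peak folds per gene were the median over the listed peaks of both lists, turned to CAR-1(FL) over CAR-1(dSm), for the 9604 genes with at least 4 listed peaks and a locus of at most 100000 bases. Their median was −0.14, and random lists for them were matched on number of peaks.

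Genes were named by a rule fixed before the data were examined: car-1, micu-1 and mcu-1 always; the 12 largest differences per direction among genes with an FPKM of at least 5 in the higher library; the 10 peaks per direction with the highest −log10 p past the thresholds, at most 1 per gene; and up to 4 members per list with an FPKM of at least 5. This gave 94 genes, of which the text names part. List members with a peak past the thresholds, C05D2.16, F38E11.24 and the genes named in the closing section outside this rule were chosen after their values were seen.

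The procedures were tested on simulated data. For CAR-1(FL) against CAR-1(dSm), 1696 genes with at least 20 implied fragments were simulated with 200 changed; 83% of genes changed by 2 log2 units and 25% of those changed by 1 unit were found at a difference of at least 1, as were 1.0% of unchanged genes. Of 100 unchanged lists of 30 genes 4 lay outside the middle 95% of random lists, and all 100 lists raised by 1 unit lay above it. Genes were simulated with Poisson counts at equal depth, so these rates do not describe genes below 20 implied fragments or spread beyond counting error. Read numbers were recovered for 100% of 117 simulated peaks. Their p-values were made with the same formulas that the recovery uses, so this tests the search only.

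Alternatives fixed beforehand were other peak thresholds, merging of peaks within 50 bases, stricter assignment to genes and overlap, pseudocounts of 0.1 and 5, other FPKM filters, centring on the median of all genes, use of the comparison table's FPKM, removal of ribosomal RNA genes, and a q-value limit of 0.01. Added after the values were seen were a minimum of 20 implied fragments, protein-coding genes only, genes tested in the authors' table only, peak folds in place of FPKM, removal of loci over 100000 bases and a q-value limit of 0.1. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.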

Results

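The series measured RNA bound to a tagged protein in Caenorhabditis elegans by seCLIP-seq, a form of crosslinking and immunoprecipitation with a single-end sequencing library. The protein was CAR-1, an RNA-binding protein of the LSm14 family found in P granules and processing bodies. 1 library came from a strain with the form labelled CAR-1(FL), and 1 library came from a strain with the form labelled CAR-1(dSm). Both were pulled down with GFP-trap, an anti-GFP single-domain antibody on beads. The study's title links CAR-1 to axon regrowth through calcium in mitochondria, and the comparison of both forms asks which RNAs were recovered more with one form than with the other. With 1 library per group there was no replicate, so no spread between samples could be measured and each difference below describes these libraries only.

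The expression tables listed 41560 gene names. The confidence bounds in those tables corresponded to 233959 fragments on genes in CAR-1(FL) and 369072 in CAR-1(dSm), called implied fragments below. Protein-coding genes held 30.8% of them in CAR-1(FL) and 28.6% in CAR-1(dSm). The ribosomal RNA gene rrn-2.1 alone held 25.9% and 34.1%. The authors marked 2 entries per library HIDATA in place of OK, so fragments of those entries may be missing from the sums. Shares are thus of implied fragments and not of a whole library. In all, 4361 genes had an FPKM of at least 1 in either library, and the better covered library gave a median of 8 implied fragments per gene, so most single genes were measured with wide error. The peak lists held 77986 peaks for CAR-1(FL) and 105255 for CAR-1(dSm).

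The car-1 gene itself was read first, because it bears on the labels. Its FPKM was 45.2 in CAR-1(FL), with a deposited interval of 38.8 to 51.6, and 94.3 in CAR-1(dSm), with an interval of 86.9 to 102. It was thus 2.09-fold higher in CAR-1(dSm), from 201 and 646 implied fragments. Along the gene the direction was not uniform. The most 5′ peak of the CAR-1(FL) list lay on chromosome I from 12904507 to 12904646 (ce10, plus strand), and it was 1.71-fold higher in CAR-1(FL), with 305 reads against 242 and an authors' −log10 p of 9.51. All 17 car-1 peaks of the CAR-1(dSm) list began at 12904817 or later. Each was higher in CAR-1(dSm), by log2 folds from 1.19 to 2.92. Single car-1 peaks held more reads than the implied fragments of the whole gene. The 5′ peak held 305 in CAR-1(FL), and the peak from 12905396 to 12905443 held 913 in CAR-1(dSm). The median log2 fold over the listed car-1 peaks was −1.83, CAR-1(FL) over CAR-1(dSm), so the size of the FPKM difference is uncertain. What part of the protein the label dSm refers to is not given in the sources used here, so car-1 separates the libraries without proving which is which.

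**Figure D1:**
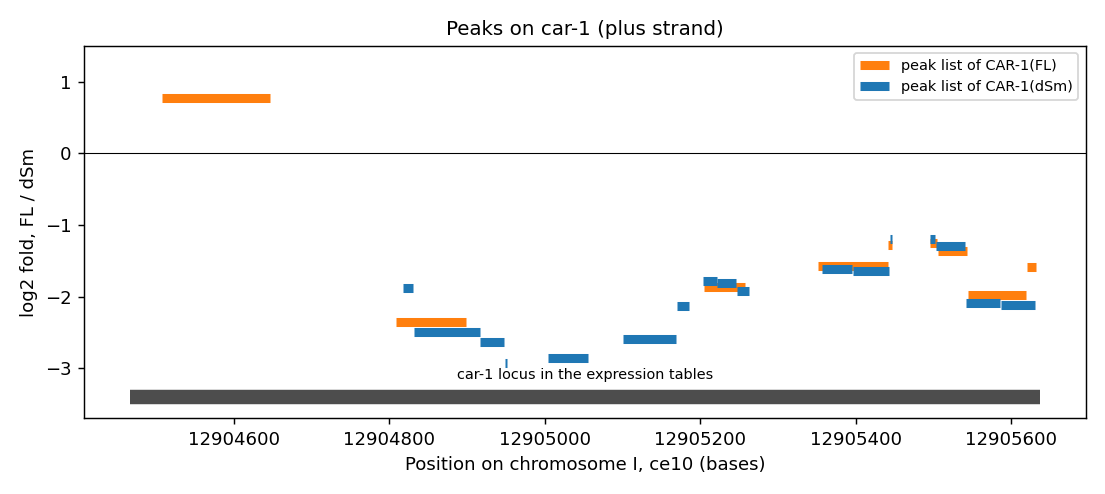
Authors' log2 fold, CAR-1(FL) over CAR-1(dSm), of every car-1 peak in both lists (y axis) against position on chromosome I in bases (x axis); each bar spans 1 peak and the grey bar is the gene's locus in the expression tables. The 5′ peak lies at 0.78 and the other 25 peaks lie between −2.92 and −1.19.

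The next question was which sites were recovered more with CAR-1(FL). Few were, and collagen genes led them. Past an authors' −log10 p of 3 and a log2 fold of 3 (8-fold), 13 peaks in 9 gene loci were higher in CAR-1(FL), with medians of 15 reads in this library and 1 in the other. The strongest lay in the cuticle collagen gene col-176 (X: 10077674 to 10077724), at 8.98-fold with 33 reads against 5. A peak in the collagen gene col-141 (V: 6829742 to 6829815) was 10.4-fold higher, with 23 reads against 3. A peak in the collagen pseudogene col-182 (X: 12636393 to 12636512) rested on 12 reads against 1. Others lay in F59C6.18 (I: 10516271 to 10516308; 21 reads against 2), in hcp-6, which encodes a condensin subunit (I: 5169840 to 5169904; 14 against 1), in K02D7.1 (IV: 296870 to 296929; 15 against 2) and in Y49G5A.1 (V: 5286704 to 5286739; 12 against 1). Of the 13 peaks, 7 had 1 read in CAR-1(dSm), a value that can also stand for none, so their folds are uncertain upward. At a log2 fold of at least 1 the number of peaks was 175.

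Sites recovered more with CAR-1(dSm) were more numerous. Noncoding RNA genes next to each other held those with the highest −log10 p, and 13 of the gene loci belonged to the neuronal list. At the same thresholds 125 peaks were higher in CAR-1(dSm), of which 7 lay in no gene locus of the tables and the rest overlapped 127 loci, with medians of 29 reads in this library and 2 in the other. The noncoding RNA gene CD4.18 held the strongest (V: 5587334 to 5587345), at 9.76-fold and the capped −log10 p of 400. Its neighbour CD4.19 followed (V: 5586984 to 5587032), at 8.25-fold with 415 reads against 37. A peak in egl-3, the proprotein convertase of neuropeptides, was 10.7-fold higher with 305 reads against 21 (V: 10170777 to 10170849). The FMRFamide-like peptide gene flp-24 had 185 reads against 14 (III: 725150 to 725197). The gene pghm-1, for an enzyme that modifies peptides, had 117 reads against 10 (I: 1808115 to 1808191). The touch-neuron α-tubulin gene mec-12 had 105 against 9 (III: 3133944 to 3134063). Further peaks among the strongest 10 lay in F10E7.9 (79 reads against 3), tag-80 (106 against 9) and clip-1 (100 against 9), and 1 peak lay in no gene locus of the tables (V: 12566085 to 12566158; 74 against 3). At a log2 fold of at least 1 the number of peaks was 2094. The CAR-1(dSm) library was 1.36 times as deep by the peak lists' own scaling, and the lists were not brought to equal depth.

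The lists were then compared by position. Of the CAR-1(FL) peaks 69.3% overlapped a CAR-1(dSm) peak on the same strand by at least 1 base, and 53.5% of the CAR-1(dSm) peaks overlapped a CAR-1(FL) peak; with at least 50% of the peak required, the shares were 58.7% and 43.1%. A single name, C05D2.16, carried peaks past the thresholds from both lists. Its locus spans 645183 bases and its FPKM was listed at 0 in both libraries.

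For micu-1, which encodes a regulator of the mitochondrial calcium uniporter, the libraries could not be told apart at this depth. Its FPKM was 0.386 in CAR-1(FL), with an interval of 0 to 1.63, and 3.02 in CAR-1(dSm), with an interval of 0.22 to 5.82; the intervals overlapped, and the values stood for 0.384 and 4.65 implied fragments. Each list held 8 micu-1 peaks and none passed the thresholds. A peak described below held 39 reads in CAR-1(dSm) and 12 in CAR-1(FL), more than the implied fragments of the whole gene. FPKM and peak reads thus disagree for micu-1, and its FPKM values are uncertain. The micu-1 peak with the highest −log10 p in the CAR-1(FL) list was 2.72-fold higher there (IV: 13299132 to 13299147; 8 reads against 4; −log10 p 0.851). Its counterpart in the CAR-1(dSm) list was 2.39-fold higher in CAR-1(dSm) (IV: 13299692 to 13299814; 39 reads against 12; −log10 p 2.01). In the authors' deposited table, whose test compares these libraries and not the conditions, micu-1 had a p-value of 0.0358 and a q-value of 0.669. The uniporter gene mcu-1 was listed at 0 in CAR-1(FL) and at 0.148 in CAR-1(dSm), and none of its 7 and 8 peaks passed the thresholds.

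By FPKM per gene, neuronal genes were higher in CAR-1(dSm) as a list, and a list made mostly of collagen genes was higher in CAR-1(FL). Most other lists lay near 0. Of the 4361 genes with an FPKM of at least 1 in either library, 624 were at least 1 log2 unit higher in CAR-1(FL), 663 were at least 1 unit higher in CAR-1(dSm), and 3074 were within 1 unit. Differences are on the log2(FPKM + 1) scale, which understates low genes, and their median was 0.07. Most of the genes beyond 1 unit were thinly covered, with a median of 1.93 implied fragments over both libraries, and 396 of the 624 and 483 of the 663 were listed at 0 in the other library. Since a listed 0 can be a failed estimate, both counts rest mostly on genes for which no fold can be given. The deposited intervals lay apart for 54 of the 624 and for 83 of the 663. These counts take in genes listed at 0 in the other library, whose interval is 0 to 0, such as col-141 and tct-1. For such genes the intervals add no evidence. The 24 named genes with the largest differences were all noncoding, among them the snoRNA gene C16D9.10 (FPKM 20127 in CAR-1(FL)) and the noncoding RNA gene M163.12 (FPKM 10952 in CAR-1(dSm)). All 24 were listed at 0 in the other library, and 23 had an interval reaching 0. The exception was the snRNA gene F38E11.10, at 755 in CAR-1(FL) with an interval of 220 to 1291 from 7.96 implied fragments. It overlaps the noncoding RNA gene F38E11.24, which went the other way (794 in CAR-1(dSm) against 284), so reads at this locus may be divided differently between both names.

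Synaptic and neuronal genes were lower in CAR-1(FL) as a group. Their median difference over 66 measured members was −0.70, below every one of 10000 random lists matched on mean expression, whose middle 95% ran from −0.18 to 0.28. Of the 66, 28 were at least 1 unit higher in CAR-1(dSm), 7 were at least 1 unit higher in CAR-1(FL) and 31 were within 1 unit. Intervals lay apart for 10 and 2, with flp-11 and flp-26, listed at 0 in CAR-1(FL), among the 10. Coverage was thin, with 459 implied fragments in CAR-1(FL) and 1251 in CAR-1(dSm) over the whole list. Only 13 members had at least 20 over both libraries. The gene egl-3 was 3.35-fold higher in CAR-1(dSm) (FPKM 2.88, interval 1.89 to 3.87, against 0.86, interval 0.057 to 1.66). The neuropeptide gene flp-26 was listed at 0 in CAR-1(FL) and at 11.9 in CAR-1(dSm), with an interval of 2.19 to 21.7. Against the group, nlp-29, an antimicrobial peptide gene of the epidermis, was 13.8-fold higher in CAR-1(FL) from 9 implied fragments against 1. Its listed peaks had a median log2 fold of only 0.14, CAR-1(FL) over CAR-1(dSm). The gene nlp-29 belongs to the epidermis list as well. The peaks gave the same direction. In the CAR-1(dSm) list 13 of the 110 neuronal genes with listed peaks carried a peak past the thresholds, against an upper limit of 3 in the middle 95% of random lists matched on number of peaks, and none did in the CAR-1(FL) list. Among them were unc-17, the vesicular acetylcholine transporter (52 reads against 4), unc-31, a factor for dense-core vesicle release (40 against 3), unc-18, a syntaxin-binding protein (35 against 3), the kinesin gene unc-104 (33 against 3), the touch-neuron β-tubulin gene mec-7 (37 against 3) and the neuropeptide genes flp-12 (74 against 5) and nlp-13 (100 against 9).

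Epidermal and collagen genes, 78 of the 92 measured being col genes, were higher in CAR-1(FL). The median over 92 measured members was 0.43, above every one of the random lists, whose middle 95% ran from −0.09 to 0.24. Of these genes, 13 were at least 1 unit higher in CAR-1(FL), none was at least 1 unit higher in CAR-1(dSm), and 79 were within 1 unit. The intervals lay apart for 19, each higher in CAR-1(FL), with col-141, listed at 0 in CAR-1(dSm), among them. The collagen gene col-176 was 6.52-fold higher (FPKM 8.90, lower bound 5.82, against 1.37, upper bound 2.33). The gene col-127 was 6.44-fold higher (5.57, lower bound 3.14, against 0.865, upper bound 1.64), and col-141 was 5.61 in CAR-1(FL) and listed at 0 in CAR-1(dSm), although its peak held 3 reads there. Collagen genes share stretches of sequence, so reads of single members may be divided differently between copies.

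**Figure D2:**
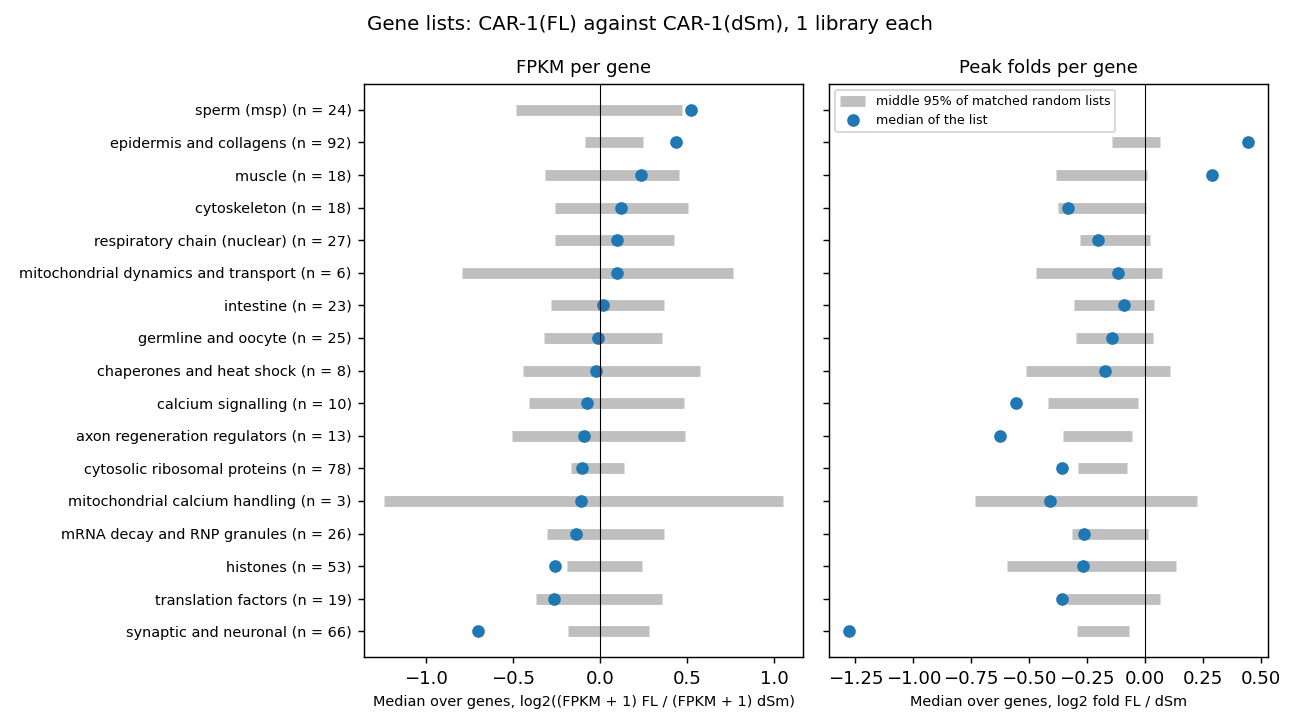
Median log2 difference, CAR-1(FL) minus CAR-1(dSm), of each gene list (points; n is the number of genes with an FPKM of at least 1) by FPKM at left and by the authors' peak folds at right, with the middle 95% of 10000 matched random lists as grey bars. Synaptic and neuronal genes lie lowest at −0.70 and −1.28, and epidermal and collagen genes lie at 0.43 and 0.44.

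Sperm genes of the major sperm protein families had a median of 0.52 over 24 measured members, at percentile 98.6 of random lists. That median rested on 47 and 50 implied fragments in all, and msp-152 stood at 5.35 in CAR-1(FL) and 0.222 in CAR-1(dSm) from 3.88 and 0.111 implied fragments. Histone genes had a median of −0.26 over 53 members, at percentile 0.68; 6 were at least 1 unit higher in CAR-1(dSm) and none in CAR-1(FL). Among them his-29 was 2.37-fold higher in CAR-1(dSm) with overlapping intervals (FPKM 15.8 against 6.68), and his-67 was listed at 0 in CAR-1(FL) and at 5.48 in CAR-1(dSm). Both families consist of near-identical copies, so single members are uncertain, and both lists fell inside the range of random lists at an FPKM of at least 5.

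The lists closest to the study's title stayed inside the range of random lists by FPKM. Axon regeneration regulators had a median of −0.10 over 13 measured members (percentile 26.3). Among them unc-70, the β-spectrin gene, was 1.94-fold higher in CAR-1(dSm) with intervals apart (FPKM 10.7, interval 9.71 to 11.7, against 5.51, interval 4.69 to 6.32). The Gq α subunit gene egl-30 was 2.22-fold higher there with overlapping intervals. Mitochondrial calcium handling had a median of −0.11 over 3 members (percentile 34.6), mitochondrial dynamics and transport 0.10 over 6 (percentile 61.7), and the nuclear respiratory chain 0.10 over 27 (percentile 48.5). The prohibitin gene phb-1 stood at 10.4 in CAR-1(FL) and 8.69 in CAR-1(dSm). Calcium signalling had a median of −0.07 over 10 (percentile 20.8); its member egl-19, a voltage-gated calcium channel gene, was 3.61-fold higher in CAR-1(dSm) with intervals apart, and the calmodulin gene cmd-1 stood at 39.3 and 36.8. When the authors' peak folds were used in place of FPKM, a measure added after the FPKM values had been seen, axon regeneration regulators (median −0.63 over 39 genes) and calcium signalling (−0.56 over 21) lay below the middle 95% of random lists.

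Genes of mRNA decay and RNP granules, the class CAR-1 belongs to, had a median of −0.14 over 26 measured members (percentile 15.7). In this list lsm-5 was 3.45-fold higher in CAR-1(FL) from 9 and 4 implied fragments, and the germline Y-box gene cey-2 was 1.35-fold higher in CAR-1(dSm) from 58.2 and 124, both with overlapping intervals. Cytosolic ribosomal protein genes had a median of −0.11 over 78 members (percentile 16.9), with 73 within 1 unit. Translation factors had a median of −0.26 over 19 (percentile 5.83), and eif-3.J stood at 6.25 in CAR-1(dSm) and 1.25 in CAR-1(FL) with intervals apart. By peak folds, ribosomal proteins (−0.36) and translation factors (−0.36) lay below the middle 95%.

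The remaining lists covered other tissues and the cytoskeleton. Muscle genes had a median of 0.23 over 18 members (percentile 80.8), and unc-89, a giant protein of the muscle M-line, was 1.69-fold higher in CAR-1(FL) with intervals apart from 483 and 428 implied fragments. By peak folds the muscle median was 0.29 over 24 genes, above every random list. Germline and oocyte genes had a median of −0.01 over 25 (percentile 47.8), where pos-1 stood at 12.9 in CAR-1(FL) and 8.38 in CAR-1(dSm). Intestinal genes had a median of 0.02 over 23 (percentile 37.5), and the desaturase gene fat-2 stood at 66.3 and 80.7. Cytoskeletal genes had a median of 0.12 over 18 (percentile 52.6). In that list unc-33, an axonal microtubule regulator, was 1.93-fold higher in CAR-1(dSm) with intervals apart. Chaperone genes had a median of −0.03 over 8 (percentile 35.3), and daf-21, which encodes HSP90, stood at 26.7 and 30.3. No gene of the mitochondrial genome was measured in the expression tables.

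FPKM differences were then read for the genes that carried strong peaks. Both measures come from the same libraries, so the selection favours a difference of the same sign. They do not count reads alike. In CAR-1(dSm) the egl-3 peak held 305 reads against 34.0 implied fragments of the whole gene, and the flp-24 peak 185 against 14.7. In CAR-1(FL) the col-176 peak held 33 reads against 33.4 implied fragments. The reason was not tested. Of 126 genes with a peak past the thresholds in the CAR-1(dSm) list alone, 38 were measured and had a median difference of −0.79; over all 126, with no filter on FPKM, it was −0.12. Of the 38, 17 were at least 1 unit higher in CAR-1(dSm) and 2 were at least 1 unit higher in CAR-1(FL). The 3 measured genes with such a peak in the CAR-1(FL) list alone had a median of 2.07, but over all 8 such genes, with no filter on FPKM, the median was 0, and F59C6.18, Y49G5A.1 and col-182 were listed at 0 in both libraries. The 4320 genes with neither had a median of 0.08. Across 1763 genes, which are not independent replicates, the FPKM difference and the median peak fold correlated at Pearson r = 0.57 and Spearman rho = 0.53. Not every strong peak showed in its gene's FPKM: pghm-1 stood at 4.45 in CAR-1(FL) and 5.50 in CAR-1(dSm), and hcp-6 at 0.940 and 0.920.

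The authors' own gene test called nothing. In the authors' deposited table, which compares these libraries and not the conditions, 3278 genes were tested and 0 were called significant. Among the genes tested and not called were unc-70, unc-33, eif-3.J, unc-89 and egl-19, whose deposited intervals lay apart. The lowest q-value in the authors' deposited table was 0.082, shared by 2 genes, CD4.18, higher in CAR-1(dSm), and col-141, higher in CAR-1(FL). In the per-library tables CD4.18 had an FPKM of 53755 in CAR-1(dSm) against 4347 in CAR-1(FL), 12.4-fold, with intervals apart. In the authors' deposited table, an unadjusted p-value of at most 0.05 was given to 169 genes, or 5.16% of those tested. Of these genes in the authors' deposited table, 109 were lower in CAR-1(FL) and 60 higher.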

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

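Peaks on the mitochondrial chromosome entered the counts and overlaps of all listed peaks but no comparison by gene, because no gene of that chromosome has a row in the expression tables. The CAR-1(FL) list held 118 peaks there and the CAR-1(dSm) list held 111, all on the plus strand. In the CAR-1(FL) list 59 of them had an authors' −log10 p of at least 3, 18 were at the cap of 400, and their median log2 fold over CAR-1(dSm) was 0.57. In the CAR-1(dSm) list 2 had a −log10 p of at least 3, and the median log2 fold over CAR-1(FL) was −0.51. None passed the log2 fold of 3 in either list. No explanation was tested.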

How the results depend on the processing

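Of the 4 list medians outside the range of random lists, none turned to the other sign under the alternatives run; of the 13 inside it, 6 changed sign, such as calcium signalling (−0.07 to 0.03 without a filter) and the cytoskeleton (0.12 to −0.33 by peak folds). No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Median differences of neuronal genes (−0.98 to −0.24) and of epidermal and collagen genes (0.23 to 0.57) stayed outside the range of random lists under every FPKM alternative run; centring, which moves a list and its random lists alike, says nothing on this. Counts depend on thresholds by construction. At a −log10 p of at least 5 there were 4 peaks higher in CAR-1(FL) and 61 higher in CAR-1(dSm), and the genes carrying such peaks numbered 3 and 55. At a log2 fold of at least 1 there were 175 and 2094 peaks, and 145 and 662 genes. At a log2 fold of at least 4 there were 5 and 15 peaks, and 18 genes carried the latter kind; peaks in no gene locus count among the peaks only. Counting only peaks inside a single locus left 5 and 73 genes. Requiring 50% of the peak to overlap gave 58.7% and 43.1% shared peaks. Among peaks past the main or the stricter thresholds 0% were shared, which their opposite folds in the same libraries fix beforehand. Genes at least 1 unit higher, 624 in CAR-1(FL) and 663 in CAR-1(dSm), numbered 921 and 842 with a pseudocount of 0.1, which turns their balance, 260 in CAR-1(FL) and 298 in CAR-1(dSm) with a pseudocount of 5, 309 and 338 at an FPKM of at least 5, and 1875 and 2034 with the comparison table's larger FPKM. With restrictions added after the values were seen they numbered 46 and 59 at 20 implied fragments or more and 402 and 391 among protein-coding genes, where the balance turned too. At a q-value of at most 0.1, also added, 2 genes passed in the authors' deposited table, against 0 called significant. Settings that left fewer than 3 members of a list gave no value, among them sperm genes at 20 implied fragments or more and genes with a strong CAR-1(FL) peak at an FPKM of at least 5.

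Of lists outside the range of random lists, sperm genes had medians of 0 without a filter, 0.49 at an FPKM of at least 5 (3 genes) and 0.34 among genes the authors tested, all inside the range. Histones had −0.20 at an FPKM of at least 5, −0.14 at 20 implied fragments or more, −0.15 among genes the authors tested and −0.27 by peak folds, all inside the range. Genes with a strong CAR-1(FL) peak had a median of 0 with no filter. Translation factors moved outside the range among protein-coding genes (percentile 1.94 against 5.83, with a median of −0.26 from 19 genes in each case). By the authors' peak folds ribosomal proteins (−0.36), translation factors (−0.36), axon regeneration regulators (−0.63), calcium signalling (−0.56) and muscle (0.29) moved outside it. The cause was not tested for these lists. Depth limits single genes: 1696 of the 4361 genes had 20 implied fragments or more.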

Other observations

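Small noncoding RNAs also separated the libraries, in classes chosen after their values were seen. Spliced leader genes, whose RNAs are joined to the 5′ ends of mRNAs, were lower in CAR-1(FL). The SL2 genes had a median difference of −1.61 over 15 measured genes, below every matched random list, and all 10 with at least 20 implied fragments were lower in CAR-1(FL). An example was sls-2.12, 6.81-fold higher in CAR-1(dSm) with 93.7 implied fragments there. The SL1 genes had a median of −1.06 over 6 (percentile 0.59). All snRNA genes together, with these SL1 and SL2 genes among them, had a median of −1.05 over 59. The snoRNA genes went the other way, with a median of 0.29 over 130 (percentile 98.5) and 31.7% of implied fragments in CAR-1(FL) against 25.7% in CAR-1(dSm). Ribosomal RNA held 26.9% and 34.6% of implied fragments, a direction set by rrn-2.1 (log2 difference −0.44). The other 4 measured rRNA genes were higher in CAR-1(FL), and the median over the 5 measured of 12 listed was 0.98.

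3 noncoding RNA genes lay near each other on chromosome V and were all higher in CAR-1(dSm). They were CD4.18 (12.4-fold), CD4.19 (6.47-fold; FPKM 2004 against 310) and C18C4.17 (4.78-fold; 1940 against 406), the last lying from 5576206 to 5576357 inside the locus of the kinesin light chain gene klc-2. Neuropeptide genes, a large part of the neuronal list, were lower in CAR-1(FL), with medians of −1.12 over 21 flp genes and −1.15 over 27 nlp genes. The neuronal list without them was not computed. The flp genes held 22 implied fragments in CAR-1(FL) and 120 in CAR-1(dSm), and 1 of them had at least 20. Not all nlp genes went this way. The 4 with at least 20 implied fragments had a median of 0.92. Of these, nlp-24 (1.12), nlp-27 (1.25) and nlp-33 (0.72) were higher in CAR-1(FL), and nlp-13 (−1.64) was lower. By FPKM the thinly covered epidermal gene nlp-29 was higher in CAR-1(FL) too, so the nlp genes, taken by symbol, need not all be neuronal. Together the nlp genes held 0.062% of implied fragments in CAR-1(FL) and 0.045% in CAR-1(dSm).

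All tests in the next 3 paragraphs were chosen after the results they bear on were seen. Neuronal genes were higher in CAR-1(dSm) while epidermal and collagen genes were higher in CAR-1(FL). Thin coverage is argued against only in part by the 13 neuronal genes with at least 20 implied fragments over both libraries, whose median was −0.69 (percentile 0.02). Some of them passed mainly through CAR-1(dSm), such as egl-3 with 34.0 there and 4.58 in CAR-1(FL). Others were covered in both, such as ida-1 with 99.9 and 32.7. The filter sums both libraries and CAR-1(dSm) is deeper, so genes high there pass it more easily. The median of genes covered in both was not computed. More RNA of all other tissues alike in CAR-1(FL) would give these tissues one common fold, but the median peak fold of epidermal genes exceeded that of germline genes by 0.58 in log2, with a 95% bootstrap range over genes of 0.46 to 0.67. Epidermal genes also exceeded intestinal genes (0.53; 0.36 to 0.64), and muscle genes exceeded germline (0.43; 0.26 to 0.55) and intestinal genes (0.38; 0.18 to 0.53). The other pairs of these tissues did not move apart beyond their ranges: muscle minus epidermal genes was −0.15 (−0.31 to 0.01) and intestinal minus germline genes was 0.05 (−0.06 to 0.20). Of the 178 members of the epidermal list 156 were col genes, so this list need not stand for the whole tissue. A difference in the RNA bound by the CAR-1 forms cannot be told apart from a difference between the strains, cultures or pulldowns. By FPKM car-1 itself was 2.09-fold higher in CAR-1(dSm), and neither tagged protein nor input RNA was measured in the tables used.

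For the opposite directions of snoRNA and spliced leader genes, selection of RNA by length and reads split between gene copies were weighed. Among genes of 90 to 130 bases with at least 20 implied fragments, the median of 29 snoRNA genes exceeded that of 11 spliced leader genes by 1.88, with a 95% bootstrap range of 1.27 to 2.26, which length alone does not give. Summed over all SL2 genes, the share of implied fragments was 0.291% in CAR-1(dSm), with a 95% Wilson interval of 0.274% to 0.309%. In CAR-1(FL) it was 0.105%, with an interval of 0.093% to 0.119%, and the ratio of CAR-1(dSm) to CAR-1(FL) was 2.77. The Wilson intervals cover counting error only. Implied fragments come from bounds that also cover read assignment, so their sum need not restore reads split between copies. The split of reads between copies thus stays open. A difference between the CAR-1 forms and one between the pulldowns also stay open and were not tested.

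On car-1, exchanged library labels and one change in car-1 RNA level were weighed. Right and exchanged labels cannot be told apart here: the 5′ peak had a log2 fold of 0.78, but which direction an exchange predicts depends on the part of the gene that the dSm form lacks or alters, and the labels do not state it. One change of RNA level would move every peak the same way, but the highest of the other 25 peaks was at −1.19. A mixture of RNA from the endogenous gene and from a tagged copy that differ near the 5′ end was not tested and stays open.

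Some values of single genes disagreed between measures. The translationally controlled tumour protein gene tct-1 was listed at 0 in CAR-1(FL) and at 58.6 in CAR-1(dSm), while its 17 listed peaks had a median log2 fold of 0.00. The gene ubl-1 stood at 410 in CAR-1(FL) and 64.7 in CAR-1(dSm), a 6.34-fold difference from 11.7 and 10.8 implied fragments. Its 6 listed peaks had a median log2 fold of 1.30. Other genes overlap both loci, F25H2.14 and F25H2.16 in tct-1 and H06I04.8 and H06I04.9 in ubl-1. The snoRNA gene H06I04.8 was itself 4.48-fold higher in CAR-1(FL). Peaks were assigned to every locus they overlapped, so these peaks need not be those of tct-1 or ubl-1. Of 2308 genes with at least 5 implied fragments in each library, 11 had an FPKM per implied fragment more than 2-fold away from the usual ratio between the libraries.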
